A study of Mus musculus with 24 samples.

How the data were processed

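RNA of the left ventricle was measured by sequencing in mouse hearts 2, 4, 7 and 21 days after TAC or a sham operation, with 3 libraries per operation and day and 24 in all. Per the labels, ventricles were frozen in liquid nitrogen, libraries were made from total RNA with a NuGEN Ovation kit, and sequencing was on an Illumina NextSeq500. The processing notes of the labels name TopHat, DESeq and the build hg19, each without a version or settings. A human build cannot have given the mouse gene symbols in the tables, so that the mouse build, the annotation and the counting tool are not given in the sources used here.

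The authors deposited a table of raw read counts per gene symbol with 24015 genes and a table of RPKM (reads per kilobase and 1000000 reads) made by the authors with 23951 genes. All values of the count table were whole numbers, and 5355 genes had a count of 0 in every library. Of the zero counts, 10.8% had an RPKM above 0, and 159 genes with a count of 0 in every library had a mean RPKM of at least 1, so that the RPKM table was made with another counting. The comparisons rest on the counts, and the RPKM served as an alternative.

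The libraries held 10.7 to 17.6 M counted reads (M, 1000000 reads), and the tested genes held 99.96% of these. The most abundant gene took 8.25% to 10.0% of a library and the 10 most abundant 18.3% to 23.3%. The biological coefficient of variation was 0.146. The spread between libraries, not counting noise, set the precision: between replicates of a group the chi-square per degree of freedom was 3.52 to 58.9.

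In R 4.3.3 with edgeR 4.0.16, genes were kept by filterByExpr on the groups, which left 13816, and libraries were scaled by TMM. A quasi-likelihood model (glmQLFit, glmQLFTest) with 8 group means had 16 residual degrees of freedom. TAC was compared with sham at each day and averaged over days, and the effect of TAC was compared between days as day 4 minus day 2, day 7 minus day 4, day 21 minus day 7, day 21 minus day 2 and over all days at once. Sham hearts were compared over the 4 days. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Log2 fold changes come from edgeR with its prior count, and those of genes with few reads in a group depend on it.

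Before the data were examined, 34 gene lists of cell types and pathways, the alternatives below and the rule for naming genes were fixed. The lists are hypertrophic marker genes, sarcomere, calcium handling, potassium and sodium channels, fatty acid oxidation, oxidative phosphorylation, TCA cycle, glycolysis, branched-chain amino acid catabolism, extracellular matrix, activated and resident fibroblasts, TGF-beta pathway, macrophages, neutrophils, lymphocytes, cytokines and chemokines, interferon response, endothelium, pericytes and smooth muscle, cell cycle, immediate early genes, unfolded protein response, cytoskeleton, antioxidant response, glucocorticoid and fasting response, circadian clock, and atrial, epicardial, adipocyte, Schwann, skeletal muscle, blood and sex-linked genes. The lists for epicardium, with 2 measured members, and for sex were not tested. The other 32 were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. The 128 tests over the days were adjusted together, and those of day 21 minus day 2 apart. No call held with an estimated correlation at any day or for day 21 minus day 2, and its p-values stand beside the calls. For every list called, the median, the mean and the test had the same sign. Up and down counts are of members with an adjusted p under 0.05 over all genes, and counts adjusted over the list alone stand beside them.

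For each day the rule named the 6 largest and 6 smallest log2 fold changes among genes past the test with an average log2 CPM of at least 3 and no overlap between the 3 TAC and 3 sham libraries, which chance gives in 10% of genes. It named Nppa, Nppb, Myh7, Myh6, Acta1, Ankrd1, Atp2a2, Col1a1, Col3a1, Postn, Timp1 and Ctgf at every day, and for each list up to 4 members with the smallest p and any member past the test against the list. For day 21 minus day 2 and the average it named the 6 largest and 6 smallest without the overlap criterion, and for the sham hearts the 10 with the smallest p. Gene models without a name were passed over, and which of the genes so named are printed was chosen with their values in view.

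The test was tried on simulated data with 13816 genes, of which 200 were changed. Of genes changed 2-fold, 69%, 68%, 77% and 68% were found at days 2, 4, 7 and 21, and of genes changed 1.5-fold 36%, 27%, 40% and 38%, with 2.78%, 2.06%, 5.65% and 7.02% of calls false. Of 100 unchanged and 20 raised lists, camera called 0 and 20 at each day. How it does on lists whose genes vary together was not tested.

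Alternatives were RLE scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom with quality weights, the replicate number as a block within day, a fold threshold of 2, limma-trend on log2(RPKM + 1) and log2(RPKM + 0.1) with an RPKM of 1 in 3 libraries or no filter, the 6 libraries of a day alone, camera with an estimated correlation and fry, adjusted p thresholds of 0.01 and 0.1 for overlaps, and leaving out each library in turn. After the data were seen, Myl7 as a covariate and a fit without the 4 libraries over 30 CPM of Myl7 were added, as was leaving out each library for overlaps. Other splits of the libraries were counted as 10 for each day and 100 drawn with a fixed seed for the other comparisons, for differences between days also with each gene's average effect taken out by an offset. No library was left out of the main comparisons, and the RPKM of genes absent from the counts were tested apart.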

Results

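RNA of the mouse left ventricle was sequenced 2, 4, 7 and 21 days after transverse aortic constriction (TAC), an operation that narrows the aorta and puts the left ventricle under pressure overload, or after a sham operation. The 8 groups, set by operation and day, held 3 libraries each, 24 in all. Per library 10.7 to 17.6 M reads (M, 1000000 reads) were counted, and 13816 genes passed the filter on low counts. Effects are given as log2 fold changes of TAC over sham ± standard error (SE), and abundance as counts per 1000000 reads (CPM), mean ± SD of n = 3 libraries per group. CPM of a group are scaled by TMM (trimmed mean of M-values) factors, and CPM given for a single library are not. Adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and those of gene lists from limma's camera. The labels do not say whether the 3 replicates of a group are separate animals, and if they are not, the p-values measure only the spread between these samples. Genes are named by the symbols in the files, which give no positions, and no coordinates are printed because the mouse genome build is not given in the sources used here. Whether the libraries kept the strand of the RNA is not stated either, so that reads of antisense transcripts and of close paralogs may be counted under some symbols.

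At day 2 genes of the fetal and stressed heart muscle cell were higher after TAC. Myh7, the slow myosin heavy chain of the fetal mouse ventricle, went from 194 ± 173 to 2845 ± 1231 CPM (log2 fold change 3.88 ± 0.73, adjusted p = 0.00822). Nppa, which encodes atrial natriuretic peptide, went from 189.5 ± 60.5 to 1121 ± 396 CPM (2.57 ± 0.49), and Acta1, the skeletal alpha-actin, from 197 ± 44.3 to 929 ± 254 CPM (2.24 ± 0.43). Of the hypertrophic marker genes, 12 of 15 measured members rose, 15 adjusted over the list alone. The hypertrophic marker genes had a median log2 fold change of 1.92 (camera adjusted p = 1.87e-15, 0.255 with estimated correlation). The cytoskeleton list moved the same way, with tubulins such as Tubb6 (1.56 ± 0.31) and Tuba1b (1.24 ± 0.27) higher: 17 of 26 measured members rose, 23 adjusted over the list alone. The cytoskeleton list had a median log2 fold change of 0.67 (camera adjusted p = 2.93e-16, 0.255 with estimated correlation). Scn4b, a beta subunit of sodium channels, fell from 31.03 ± 11.03 to 4.99 ± 1.49 CPM (-2.66 ± 0.42), and Kcnv2, a modifier subunit of potassium channels, from 23.1 ± 5.19 to 8.74 ± 4.16 CPM (-1.42 ± 0.34). Of the potassium and sodium channels, 2 of 22 measured members fell, 3 adjusted over the list alone. The list had a median log2 fold change of -0.38 (camera adjusted p = 1.08e-05, 0.393 with estimated correlation). Of the genes of branched-chain amino acid catabolism, 2 of 17 measured members fell, 2 adjusted over the list alone, among them Bckdhb (-0.61 ± 0.17) and Pcca (-0.41 ± 0.11). The list had a median log2 fold change of -0.26 (camera adjusted p = 4.91e-06, 0.393 with estimated correlation). The lists of fatty acid oxidation (median -0.33), oxidative phosphorylation (-0.21) and the TCA cycle (-0.25) were lower as lists (camera adjusted p = 3.48e-08, 1.39e-07 and 8.07e-06; adjusted p = 0.424, 0.551 and 0.455 with estimated correlation). In these lists 0 members passed edgeR's test over all genes or over the list alone, 9, 4 and 2 members were lower at an unadjusted p under 0.05, DESeq2 called 0 and voom 23, 35 and 18. Myh6, the fast adult myosin heavy chain, had a log2 fold change of -0.36 ± 0.201 (adjusted p = 0.338) and Atp2a2, the calcium pump of the sarcoplasmic reticulum, -0.42 ± 0.18 (adjusted p = 0.181).

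Genes of dividing cells were higher at day 2, as were genes of macrophages and of protein folding. Mki67, a proliferation marker, went from 18.0 ± 3.13 to 92.4 ± 60.6 CPM (2.36 ± 0.42) and Top2a, a topoisomerase of dividing cells, from 2.30 ± 0.795 to 17.3 ± 12.2 CPM (2.92 ± 0.51). Of the cell cycle genes, 25 of 36 measured members rose, 32 adjusted over the list alone. The cell cycle list had a median log2 fold change of 1.83 (camera adjusted p = 2.20e-22, 0.255 with estimated correlation). Of the macrophage and monocyte markers, 10 of 25 measured members rose, 14 adjusted over the list alone, with Spp1, which encodes osteopontin, at 6.39 ± 1.13 and Itgam, an integrin of myeloid cells, at 1.61 ± 0.30. The macrophage and monocyte markers had a median log2 fold change of 0.78 (camera adjusted p = 4.61e-09, 0.342 with estimated correlation). Of the cytokines and chemokines, 6 of 28 measured members rose, 15 adjusted over the list alone, among them the monocyte attractant Ccl2 (2.61 ± 0.57). The cytokines and chemokines list had a median log2 fold change of 1.22 (camera adjusted p = 4.64e-08, 0.342 with estimated correlation). Among the neutrophil markers Lcn2, a lipocalin of neutrophils and stressed tissue, rose from 8.70 ± 3.90 to 35.2 ± 6.19 CPM (2.02 ± 0.31), and 1 of 6 measured members rose, 2 adjusted over the list alone. The neutrophil markers had a median log2 fold change of 0.94 (camera adjusted p = 0.00428, 0.291 with estimated correlation). Of the genes of the unfolded protein response, 10 of 21 measured members rose, 12 adjusted over the list alone, among them Pdia6 (0.87 ± 0.15) and Manf (1.05 ± 0.195). The unfolded protein response list had a median log2 fold change of 0.48 (camera adjusted p = 3.63e-10, 0.255 with estimated correlation). The immediate early genes include Ier3 (0.93 ± 0.18) and Myc (1.49 ± 0.34), and 5 of 23 measured members rose, 11 adjusted over the list alone. The immediate early genes had a median log2 fold change of 0.45 (camera adjusted p = 6.13e-07, 0.255 with estimated correlation). Of the antioxidant response genes, 3 of 17 measured members rose, 4 adjusted over the list alone: heme oxygenase Hmox1 (2.69 ± 0.52), the metallothionein Mt2 (1.35 ± 0.22) and Gpx1 (0.49 ± 0.12). The antioxidant response list had a median log2 fold change of 0.26 (camera adjusted p = 0.00489, 0.255 with estimated correlation).

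In the lists of matrix and activated fibroblasts, few genes passed edgeR's test at day 2. Of 43 and 16 members, 20 and 9 were higher at an unadjusted p under 0.05. DESeq2 called 5 and 2 and voom 31 and 8. Of the extracellular matrix genes, 2 of 43 measured members rose, 6 adjusted over the list alone, namely Tnc, a matrix glycoprotein of injured tissue (5.34 ± 3.02 to 154 ± 153 CPM, 4.88 ± 0.87), and the protease inhibitor Timp1 (4.06 ± 0.83). The list had a median log2 fold change of 0.72 (camera adjusted p = 3.36e-07, 0.551 with estimated correlation). The fibrillar collagens Col1a1 and Col3a1 had log2 fold changes of 1.15 ± 0.53 (adjusted p = 0.225) and 1.21 ± 0.47 (adjusted p = 0.143), and Postn, the matrix protein periostin, of 1.75 ± 0.61 (adjusted p = 0.110). Of the activated fibroblast markers, 2 of 16 measured members rose, 6 adjusted over the list alone, Ctgf (2.43 ± 0.48) and Cnn1 (2.73 ± 0.64). The list had a median log2 fold change of 1.09 (camera adjusted p = 8.48e-05, 0.393 with estimated correlation). Of the TGF-beta pathway, 4 of 16 measured members rose, 5 adjusted over the list alone, among them Tgfb2 (1.38 ± 0.39). The list had a median log2 fold change of 0.27 (camera adjusted p = 0.00243, 0.478 with estimated correlation). Endothelial genes were lower: 3 of 20 measured members fell, 6 adjusted over the list alone, namely the receptors Kdr (-0.61 ± 0.12), Tie1 (-0.52 ± 0.10) and Tek (-0.30 ± 0.085). The endothelial markers had a median log2 fold change of -0.27 (camera adjusted p = 2.26e-07, 0.255 with estimated correlation). Of the interferon response genes, 1 of 18 measured members fell, 1 adjusted over the list alone, and the member was Rsad2 (-0.73 ± 0.18). The list had a median log2 fold change of -0.25 (camera adjusted p = 0.00276, 0.551 with estimated correlation). Of the atrial markers, 1 of 7 measured members fell, 2 adjusted over the list alone, and the member past the test was Stard10 (-1.07 ± 0.24). The atrial markers had a median log2 fold change of -2.88 (camera adjusted p = 0.0215, 0.455 with estimated correlation). Myl7, an atrial myosin light chain, was at 37.2 and 94.8 CPM in sham replicates 2 and 3 of this day. Esr1, the estrogen receptor alpha, had a mean of 1.43 ± 0.165 to 704 ± 1214 CPM from sham to TAC (8.94 ± 1.77), with 2003 CPM in TAC replicate 1 and at most 3.42 CPM in each of the other 11 TAC libraries. Across all genes, 633 passed the test at day 2, 515 higher and 118 lower.

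That count was 112, 12 and 96 without sham replicates 1, 2 and 3 of day 2 and 1835, 352 and 12 without TAC replicates 1, 2 and 3. Over all tested genes TAC replicate 1 had a slope of 0.0794 on the mean effect of TAC at the other 3 days, within the range of sham hearts (-0.125 to 0.0817). Of the 58 genes named by rule that passed, Fah (-1.14 ± 0.16) and Lcn2 kept their call without each library of the day while 56 lost it without 1 or more, 55 of them without sham replicate 2. The neutrophil list had an adjusted p = 0.0580 without TAC replicate 3, and the atrial list of 0.0761 and 0.292 without sham replicates 2 and 3 and of 0.148 without TAC replicate 1. Without the 4 libraries that held over 30 CPM of Myl7, an alternative chosen after seeing the data, edgeR called 0 genes at day 2 (1447 at an unadjusted p under 0.05), and no other tool was run on those libraries, which held 1 sham heart of day 2. With Myl7 as a covariate, chosen likewise, it called 1552.

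**Figure D1:**
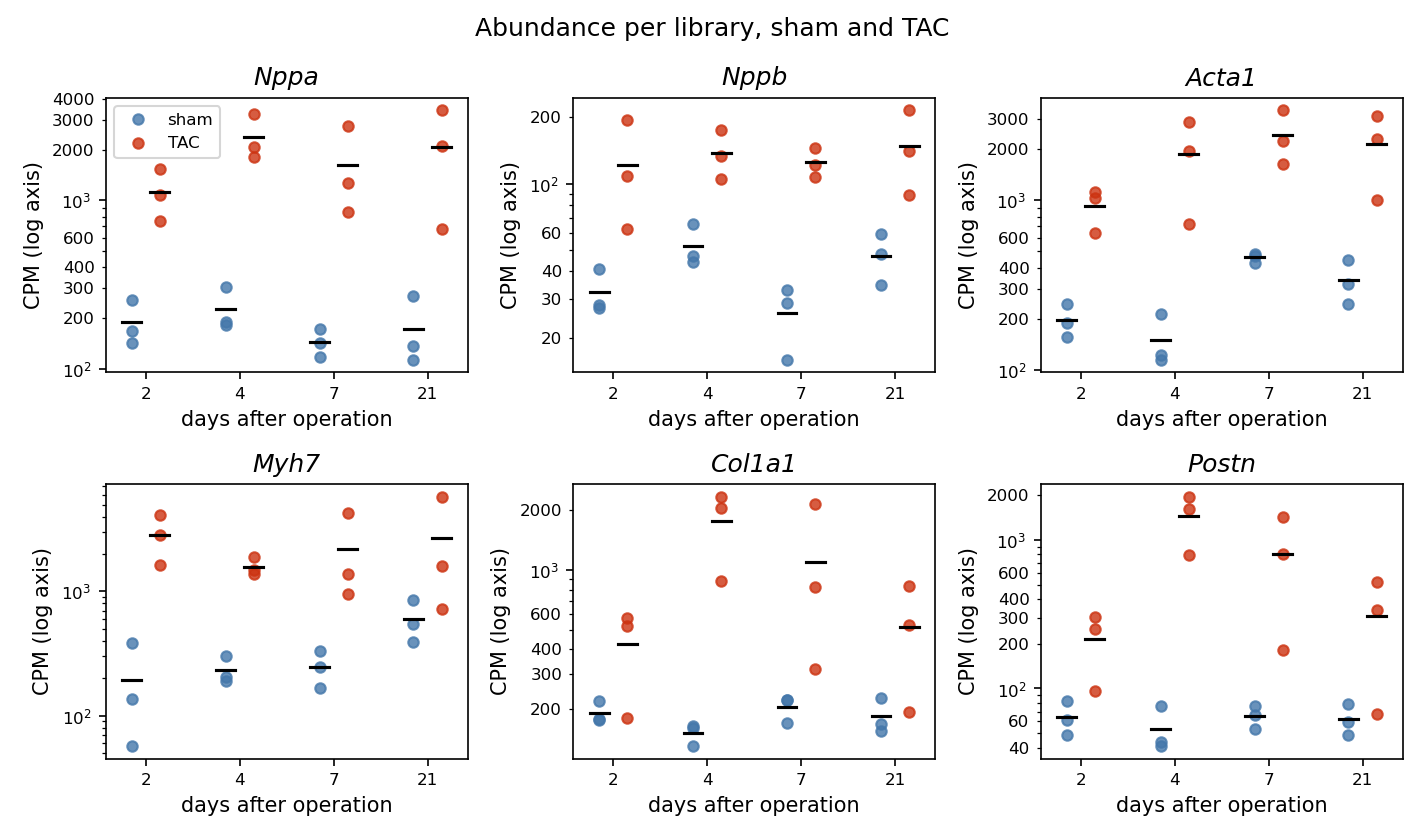
CPM on a log axis of 4 genes of stressed heart muscle and 2 matrix genes in each of the 24 libraries, by day, with group means as lines. Nppa lies above all 12 sham libraries in each of the 12 TAC libraries, and the mean of Col1a1 at day 4 goes from 152 ± 19.01 to 1764 ± 774 CPM.

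At day 4 genes of the matrix, of dividing cells and of immune cells were higher. Postn went from 53.5 ± 19.3 to 1451 ± 594 CPM (log2 fold change 4.76 ± 0.69, adjusted p = 0.000226), Col1a1 from 152 ± 19.01 to 1764 ± 774 CPM (3.53 ± 0.58) and Tnc from 3.94 ± 2.93 to 382 ± 161 CPM (6.59 ± 0.94). Of the extracellular matrix genes, 38 of 43 measured members rose, 39 adjusted over the list alone. The extracellular matrix list had a median log2 fold change of 2.13 (camera adjusted p = 3.74e-23, 0.342 with estimated correlation). Of the activated fibroblast markers, 13 of 16 measured members rose, 14 adjusted over the list alone, among them Cthrc1, a secreted protein of matrix-making fibroblasts (6.76 ± 1.21), and Cilp (4.20 ± 0.83). The activated fibroblast markers had a median log2 fold change of 2.22 (camera adjusted p = 4.91e-09, 0.342 with estimated correlation). Of the TGF-beta pathway, 10 of 16 measured members rose, 11 adjusted over the list alone, with Tgfb1 at 0.61 ± 0.14 and Tgfb3 at 1.63 ± 0.36. The TGF-beta pathway list had a median log2 fold change of 0.66 (camera adjusted p = 0.000177, 0.397 with estimated correlation). The resident fibroblast markers went both ways: Lamc1 (0.59 ± 0.10), Col15a1 (1.49 ± 0.30) and Ddr2 (0.46 ± 0.10) were among 4 that rose, and Gsn (-0.90 ± 0.16) and Gstm5 (-0.53 ± 0.17) fell, of 14 measured (camera adjusted p = 0.266).

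At day 4 Csf1r, the receptor of the macrophage growth factor, went from 49.4 ± 5.04 to 101.05 ± 12.4 CPM (1.03 ± 0.13), and the complement gene C1qb from 36.7 ± 8.69 to 99.9 ± 11.2 CPM (1.44 ± 0.202). Of the macrophage and monocyte markers, 20 of 25 measured members rose, 21 adjusted over the list alone. The macrophage and monocyte markers had a median log2 fold change of 1.53 (camera adjusted p = 1.99e-13, 0.255 with estimated correlation). Of the cytokines and chemokines, 18 of 28 measured members rose, 21 adjusted over the list alone, such as Cxcl10 (2.65 ± 0.56) and Cxcl16 (1.06 ± 0.23). The cytokines and chemokines list had a median log2 fold change of 1.22 (camera adjusted p = 1.75e-07, 0.346 with estimated correlation). Of the interferon response genes, 13 of 18 measured members rose, 15 adjusted over the list alone, such as the antiviral Mx1 (2.68 ± 0.45) and Oasl2 (0.97 ± 0.17). The interferon response list had a median log2 fold change of 0.78 (camera adjusted p = 2.68e-08, 0.372 with estimated correlation). Mki67 went from 29.4 ± 0.755 to 257 ± 143 CPM (3.13 ± 0.42) and Foxm1, a transcription factor of mitosis, from 1.60 ± 0.167 to 16.1 ± 11.5 CPM (3.33 ± 0.45). Of the cell cycle genes, 30 of 36 measured members rose, 34 adjusted over the list alone. The cell cycle list had a median log2 fold change of 2.85 (camera adjusted p = 2.34e-20, 0.291 with estimated correlation). Of the immediate early genes, 11 of 23 measured members rose, 11 adjusted over the list alone, among them Egr2 (3.37 ± 0.67) and Egr3 (1.96 ± 0.44), while the phosphatase Dusp1 fell (-0.88 ± 0.22). The immediate early genes had a median log2 fold change of 0.46 (camera adjusted p = 0.00428, 0.393 with estimated correlation). Of the unfolded protein response, 8 of 21 measured members rose, 8 adjusted over the list alone, with Edem1 at 1.03 ± 0.19. The unfolded protein response list had a median log2 fold change of 0.22 (camera adjusted p = 0.0102, 0.441 with estimated correlation). Of the antioxidant genes, 6 of 17 measured members rose, 7 adjusted over the list alone, among them Mt2 (1.67 ± 0.25) and Gpx3 (1.29 ± 0.27). The antioxidant response list had a median log2 fold change of 0.28 (camera adjusted p = 0.00835, 0.255 with estimated correlation).

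Genes of heart muscle stress rose at day 4, and genes of energy metabolism and ion channels fell. Nppa went from 226 ± 70.8 to 2376 ± 772 CPM (3.40 ± 0.51), Acta1 from 151 ± 55.8 to 1853 ± 1086 CPM (3.62 ± 0.45) and Myh7 from 232 ± 59.7 to 1587 ± 268 CPM (2.78 ± 0.69). Of the hypertrophic marker genes, 14 of 15 measured members rose, 15 adjusted over the list alone, and of the cytoskeleton genes, among them Tmsb10 (1.41 ± 0.22) and desmin, Des (0.69 ± 0.12), 23 of 26 measured members rose, 23 adjusted over the list alone. The hypertrophic marker genes had a median log2 fold change of 2.15 (camera adjusted p = 4.46e-12, 0.255 with estimated correlation). The cytoskeleton list had a median log2 fold change of 0.86 (camera adjusted p = 1.80e-12, 0.342 with estimated correlation). Of the genes of fatty acid oxidation, 22 of 30 measured members fell, 24 adjusted over the list alone, such as Hadhb (1049 ± 80.0 to 605 ± 112 CPM, -0.79 ± 0.17) and Eci1 (-0.89 ± 0.205). The fatty acid oxidation list had a median log2 fold change of -0.60 (camera adjusted p = 7.08e-11, 0.393 with estimated correlation). Of oxidative phosphorylation, 32 of 51 measured members fell, 41 adjusted over the list alone, such as Ndufs1 (-0.56 ± 0.12) and the ATP synthase subunit Atp5b (-0.60 ± 0.14). The list had a median log2 fold change of -0.51 (camera adjusted p = 2.57e-14, 0.393 with estimated correlation). Of the TCA cycle, 11 of 18 measured members fell, 14 adjusted over the list alone, such as Suclg2 (-0.64 ± 0.15). The TCA cycle list had a median log2 fold change of -0.47 (camera adjusted p = 1.89e-07, 0.393 with estimated correlation). Of branched-chain amino acid catabolism, 13 of 17 measured members fell, 15 adjusted over the list alone, such as Acadsb (-0.56 ± 0.085) and Pccb (-0.59 ± 0.12). The list had a median log2 fold change of -0.60 (camera adjusted p = 1.14e-09, 0.360 with estimated correlation). In the glycolysis list Pfkp (0.99 ± 0.16), Pgam1 (0.75 ± 0.16) and 3 others rose and the muscle isoforms Pfkm (-0.60 ± 0.17) and Eno3 (-0.61 ± 0.22) fell, of 18 measured (camera adjusted p = 0.373). Of the potassium and sodium channels, 10 of 22 measured members fell, 10 adjusted over the list alone, such as Kcnv2 (-2.25 ± 0.39) and Kcnj11 (-0.64 ± 0.14). The list had a median log2 fold change of -0.49 (camera adjusted p = 4.75e-05, 0.393 with estimated correlation).

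Pln, which encodes the inhibitor of the calcium pump, fell at day 4 (-0.67 ± 0.13), the exchanger Slc8a1 rose (0.46 ± 0.12), and of 19 calcium handling genes 1 rose and 4 fell (camera adjusted p = 0.0705, 0.0253 without TAC replicate 2). Endothelial genes fell as a list: 6 of 20 measured members fell, 6 adjusted over the list alone, among them the water channel Aqp1 (-0.76 ± 0.17) and Tie1 (-0.34 ± 0.10). The endothelial markers had a median log2 fold change of -0.202 (camera adjusted p = 0.00318, 0.393 with estimated correlation). Of the clock genes, 5 of 17 measured members fell, 7 adjusted over the list alone, with Nr1d1 at -0.72 ± 0.11, while Bhlhe40 (0.54 ± 0.12) and Bhlhe41 (0.51 ± 0.13) rose. The circadian clock list had a median log2 fold change of -0.42 (camera adjusted p = 0.0307, 0.434 with estimated correlation). Thrsp, a regulator of lipid synthesis, had a mean of 35.1 ± 27.3 to 13.8 ± 0.387 CPM from sham to TAC (-1.35 ± 0.39). Sham replicate 3 held 65.8 CPM of it, and also 13.4 CPM of the fat cell gene Adipoq, against at most 1.60 CPM in the other libraries. Across all genes 3394 passed the test at day 4, 1995 higher and 1399 lower. Without TAC replicate 3 of day 4 the count was 1402, and 28 of the 124 genes named by rule that passed lost their call, Gstm5, Pfkm, Eno3, Tie1 and Thrsp among them, while Slc8a1 and Alas2 lost it without TAC replicate 1. The clock list had an adjusted p = 0.0532 without sham replicate 2, 0.0939 without TAC replicate 2 and 0.0598 without TAC replicate 3, and the unfolded protein response 0.0555 without sham replicate 3, without which Thrsp also lost its call.

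After 7 days, hypertrophic marker, matrix and cell cycle genes were higher, and genes of fuel use, calcium handling and ion channels lower. Nppa went from 144 ± 27.2 to 1625 ± 1004 CPM (log2 fold change 3.497 ± 0.51, adjusted p = 0.000194). Nppb, which encodes the B-type natriuretic peptide, went from 25.8 ± 8.82 to 125 ± 18.97 CPM (2.27 ± 0.37) and Myh7 from 248 ± 80.3 to 2206 ± 1805 CPM (3.15 ± 0.70). Of the hypertrophic marker genes, 12 of 15 measured members rose, 15 adjusted over the list alone. The hypertrophic marker genes had a median log2 fold change of 1.98 (camera adjusted p = 1.48e-08, 0.342 with estimated correlation). Of the cytoskeleton genes, 18 of 26 measured members rose, 22 adjusted over the list alone, such as vimentin, Vim (1.46 ± 0.26), and Actn4 (0.60 ± 0.12). The cytoskeleton list had a median log2 fold change of 0.81 (camera adjusted p = 4.61e-09, 0.393 with estimated correlation). Col4a1, a collagen of basement membranes, went from 534 ± 37.2 to 1398 ± 215 CPM (1.39 ± 0.18). Fbn1, the microfibril protein fibrillin, went from 159 ± 13.9 to 589.5 ± 264 CPM (1.89 ± 0.31) and Postn from 65.5 ± 11.4 to 809 ± 627 CPM (3.63 ± 0.66). Of the extracellular matrix genes, 39 of 43 measured members rose, 39 adjusted over the list alone. The extracellular matrix list had a median log2 fold change of 1.87 (camera adjusted p = 9.91e-16, 0.393 with estimated correlation). Of the activated fibroblast markers, 9 of 16 measured members rose, 11 adjusted over the list alone. The activated fibroblast markers had a median log2 fold change of 1.66 (camera adjusted p = 0.000232, 0.424 with estimated correlation). Of the TGF-beta pathway, 3 of 16 measured members rose, 7 adjusted over the list alone, with Tgfb1 at 0.75 ± 0.14. The TGF-beta pathway list had a median log2 fold change of 0.59 (camera adjusted p = 0.0152, 0.580 with estimated correlation). Among the resident fibroblast markers 6 of 14 rose, such as Col15a1 (1.69 ± 0.30), and Gsn fell (-0.73 ± 0.16; camera adjusted p = 0.138).

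At day 7, of the cell cycle genes, 34 of 36 measured members rose, 34 adjusted over the list alone, such as Ccna2 (3.32 ± 0.930 to 33.2 ± 9.61 CPM, 3.32 ± 0.45) and Prc1 (3.34 ± 0.44). The cell cycle list had a median log2 fold change of 2.78 (camera adjusted p = 8.30e-25, 0.255 with estimated correlation). Of the macrophage and monocyte markers, 16 of 25 measured members rose, 19 adjusted over the list alone, such as C1qa (0.93 ± 0.21). The macrophage and monocyte markers had a median log2 fold change of 0.93 (camera adjusted p = 2.08e-06, 0.393 with estimated correlation). Of the cytokines and chemokines, 7 of 28 measured members rose, 10 adjusted over the list alone, such as Ccl8 (3.504 ± 0.68), and of the interferon response genes, among them Irf7 (1.25 ± 0.22) and Bst2 (0.90 ± 0.16), 12 of 18 measured members rose, 15 adjusted over the list alone. The cytokines and chemokines list had a median log2 fold change of 0.69 (camera adjusted p = 0.00138, 0.455 with estimated correlation). The interferon response list had a median log2 fold change of 0.76 (camera adjusted p = 4.09e-07, 0.393 with estimated correlation). Of the immediate early genes, 5 of 23 measured members rose, 5 adjusted over the list alone, such as Egr3 (2.32 ± 0.46). The immediate early genes had a median log2 fold change of 0.37 (camera adjusted p = 0.00167, 0.393 with estimated correlation). The endothelial markers parted: Aplnr, the apelin receptor (1.08 ± 0.19), Cdh5, the cadherin of endothelial junctions (0.44 ± 0.10), Pecam1 (0.41 ± 0.082) and 4 others rose. Vwf (-0.60 ± 0.15), Flt1 (-0.32 ± 0.09) and Aqp1 (-0.55 ± 0.17) fell, of 20 measured (camera adjusted p = 0.207, 0.0283 without TAC replicate 1). Mcam, an adhesion molecule of vessel cells, rose (1.21 ± 0.17), as did Cspg4 (0.70 ± 0.12) and Notch3 (0.27 ± 0.095), 3 of the 12 pericyte and smooth muscle markers (camera adjusted p = 0.0901, 0.0410 and 0.0248 without sham replicate 1 and TAC replicate 3).

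At day 7, of the genes of fatty acid oxidation, 25 of 30 measured members fell, 27 adjusted over the list alone, among them the fatty acid transporter Cd36 (1498 ± 99.8 to 951 ± 121 CPM, -0.65 ± 0.15). The fatty acid oxidation list had a median log2 fold change of -0.65 (camera adjusted p = 3.85e-13, 0.393 with estimated correlation). Ucp3, a mitochondrial carrier (-2.01 ± 0.47), and Pdk4, a kinase that restrains glucose oxidation (411 ± 219 to 113 ± 20.8 CPM, -1.86 ± 0.37), were among the 6 largest falls of the day. Of oxidative phosphorylation, 22 of 51 measured members fell, 36 adjusted over the list alone, such as Cox7c (-0.49 ± 0.10). The oxidative phosphorylation list had a median log2 fold change of -0.45 (camera adjusted p = 1.02e-13, 0.397 with estimated correlation). Of the TCA cycle, 10 of 18 measured members fell, 16 adjusted over the list alone, such as Idh3g (-0.61 ± 0.13), and of branched-chain amino acid catabolism, such as Dbt (-0.86 ± 0.14), 14 of 17 measured members fell, 15 adjusted over the list alone. The TCA cycle list had a median log2 fold change of -0.45 (camera adjusted p = 1.39e-07, 0.393 with estimated correlation). The branched-chain amino acid catabolism list had a median log2 fold change of -0.58 (camera adjusted p = 2.45e-09, 0.371 with estimated correlation). Of the calcium handling genes, 8 of 19 measured members fell, 8 adjusted over the list alone, among them the release channel Ryr2 (-0.47 ± 0.11), triadin, Trdn (-0.60 ± 0.13), Pln (-0.61 ± 0.13) and Atp2a2 (-0.68 ± 0.18). The calcium handling list had a median log2 fold change of -0.30 (camera adjusted p = 0.00110, 0.393 with estimated correlation). Of the potassium and sodium channels, 11 of 22 measured members fell, 15 adjusted over the list alone, such as Kcnj2, the inward rectifier (-0.94 ± 0.17), Kcnj5 (-0.69 ± 0.13) and Kcnv2 (-2.61 ± 0.38). The potassium and sodium channels list had a median log2 fold change of -0.57 (camera adjusted p = 1.58e-05, 0.393 with estimated correlation). Of the sarcomere genes, 4 of 20 measured members fell, 5 adjusted over the list alone, such as Tnni3 (-0.69 ± 0.22), and Myh6 had a log2 fold change of -0.55 ± 0.201 (adjusted p = 0.0510). The sarcomere list had a median log2 fold change of -0.23 (camera adjusted p = 0.00299, 0.551 with estimated correlation). Of the clock genes, 3 of 17 measured members fell, 3 adjusted over the list alone, with Nr1d1 at -0.52 ± 0.11. The circadian clock list had a median log2 fold change of -0.34 (camera adjusted p = 0.0154, 0.393 with estimated correlation). In the antioxidant list Gpx1 (0.54 ± 0.12) and 3 others rose and catalase, Cat (-0.79 ± 0.16), Sod2 (-0.50 ± 0.17) and Prdx1 (-0.22 ± 0.078) fell, of 17 (camera adjusted p = 0.957). In the unfolded protein response 2 rose and 3 fell of 21, Herpud1 (-0.70 ± 0.21) among the latter (camera adjusted p = 0.919).

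Across all genes 3201 passed the test at day 7, 1816 higher and 1385 lower. The count was 2027, 2093 and 1569 without sham replicates 1, 2 and 3 of day 7 and 1270 and 1884 without TAC replicates 1 and 3. Of the 118 genes named by rule that passed, 44 lost their call without 1 or more libraries, 42 of them without TAC replicate 1, Atp2a2, Tnni3, Flt1, Aqp1, Notch3, Sod2, Prdx1 and Herpud1 among them. TAC replicate 1 of this day held 69.2 CPM of the atrial gene Myl7, and without that library the sarcomere list had an adjusted p = 0.145 and the TGF-beta pathway 0.259.

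After 21 days the genes past the test were fewer, and Nppa, Acta1 and the basement membrane collagen Col4a1 were among those higher. Nppa went from 173 ± 84.4 to 2066 ± 1366 CPM (log2 fold change 3.58 ± 0.52, adjusted p = 0.00403) and Acta1 from 337 ± 101.33 to 2144 ± 1075 CPM (2.67 ± 0.43, adjusted p = 0.00898). Nmrk2, a kinase that feeds NAD synthesis, went from 1.22 ± 0.231 to 12.7 ± 15.0 CPM (3.39 ± 0.65). Of the hypertrophic marker genes, 5 of 15 measured members rose, 13 adjusted over the list alone. The hypertrophic marker genes had a median log2 fold change of 1.49 (camera adjusted p = 1.95e-12, 0.255 with estimated correlation). Col4a1 went from 673 ± 47.3 to 1238 ± 139 CPM (0.88 ± 0.18), Sparc from 351 ± 25.5 to 771 ± 242 CPM (1.14 ± 0.26), and of the extracellular matrix genes, 5 of 43 measured members rose, 32 adjusted over the list alone. The extracellular matrix list had a median log2 fold change of 1.14 (camera adjusted p = 4.83e-14, 0.393 with estimated correlation). Lrrc17, a secreted leucine-rich repeat protein, rose from 92.6 ± 21.9 to 237 ± 62.5 CPM (1.36 ± 0.198), and Aldh1l2, a mitochondrial enzyme of folate metabolism, fell from 17.7 ± 2.13 to 6.89 ± 0.177 CPM (-1.36 ± 0.19). Myh7 had a log2 fold change of 2.18 ± 0.67 (adjusted p = 0.108), Postn of 2.31 ± 0.63 (adjusted p = 0.0705) and Col1a1 of 1.49 ± 0.53 (adjusted p = 0.154).

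At day 21, of the interferon response genes, Bst2 (0.87 ± 0.17) and Rsad2 (0.74 ± 0.18) among them, 2 of 18 measured members rose, 11 adjusted over the list alone. The interferon response list had a median log2 fold change of 0.54 (camera adjusted p = 7.49e-09, 0.360 with estimated correlation). Of the cytoskeleton genes, 1 of 26 measured members rose, 11 adjusted over the list alone, and of the potassium and sodium channels, 1 of 22 measured members fell, 4 adjusted over the list alone, the members past the test being Tuba1c (0.99 ± 0.22) and Kcnj5 (-0.61 ± 0.13). The cytoskeleton list had a median log2 fold change of 0.44 (camera adjusted p = 4.64e-08, 0.393 with estimated correlation). The potassium and sodium channels list had a median log2 fold change of -0.21 (camera adjusted p = 7.09e-05, 0.393 with estimated correlation). Of oxidative phosphorylation, 1 of 51 measured members fell, 1 adjusted over the list alone, the member being Cox7c (-0.58 ± 0.10). The oxidative phosphorylation list had a median log2 fold change of -0.17 (camera adjusted p = 6.72e-06, 0.608 with estimated correlation). The glycolysis list was higher, with Pfkp (0.82 ± 0.16) and Hk1 (0.35 ± 0.073) past the test, and 2 of 18 measured members rose, 3 adjusted over the list alone. The glycolysis list had a median log2 fold change of 0.045 (camera adjusted p = 0.0498, 0.475 with estimated correlation). Further lists moved as lists while edgeR called 0 of their members over all genes. Lower was fatty acid oxidation (median -0.36, camera adjusted p = 2.44e-10, 0.393 with estimated correlation). So were the TCA cycle (-0.22, camera adjusted p = 3.31e-05, 0.478 with estimated correlation) and branched-chain amino acid catabolism (-0.33, camera adjusted p = 2.06e-08, 0.393 with estimated correlation). Of their 30, 18 and 17 measured members 17, 6 and 11 were lower at an unadjusted p under 0.05, DESeq2 called 1, 0 and 3 and voom 18, 7 and 11, and adjusted over the list alone 6, 0 and 6 fell. Higher were the macrophage markers (0.55, camera adjusted p = 1.34e-05, 0.393 with estimated correlation) and cell cycle genes (0.67, camera adjusted p = 4.05e-06, 0.478 with estimated correlation). The activated fibroblast markers (0.998, camera adjusted p = 0.00752, 0.551 with estimated correlation) and cytokines and chemokines (0.47, camera adjusted p = 0.0114, 0.551 with estimated correlation) were higher, too. The TGF-beta pathway (0.24, camera adjusted p = 0.0365, 0.608 with estimated correlation) and the endothelial markers (0.18, camera adjusted p = 0.00875, 0.427 with estimated correlation) were among these lists. Others were the pericyte and smooth muscle markers (0.19, camera adjusted p = 0.0161, 0.393 with estimated correlation) and the lymphocyte markers (0.85, camera adjusted p = 0.0233, 0.342 with estimated correlation). Of these 8 lists the macrophage markers had 9 of 25 members higher at an unadjusted p under 0.05, cell cycle 8 of 36, and activated fibroblasts 7 of 16. For cytokines it was 2 of 28, TGF-beta 4 of 16, endothelial 7 of 20, pericyte and smooth muscle 4 of 12 and lymphocytes 1 of 5. In the same order DESeq2 called 1, 2, 2, 0, 1, 1, 2 and 0 and voom 5, 6, 5, 1, 4, 6, 5 and 0. Adjusted over the list alone it was 1, 0, 5, 0, 3, 1, 3 and 0.

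Across all genes 151 passed the test at day 21, 86 higher and 65 lower, and the count was 17, 28 and 7 without sham replicates 1, 2 and 3 of day 21 and 8, 575 and 9 without TAC replicates 1, 2 and 3. Over all tested genes TAC replicate 2 had a slope of 0.0763 on the mean effect of TAC at the other 3 days, within the range of sham hearts (-0.125 to 0.0817). Of the 25 genes named by rule that passed, Nppa, Lrrc17 and Aldh1l2 kept their call without each library of the day and 22 lost it without 1 or more, 21 of them without sham replicate 3, and sham replicate 2 held 69.9 CPM of Myl7. Without the 4 libraries over 30 CPM of Myl7 the count was 3, and with Myl7 as a covariate 1153. Leaving out TAC replicate 3 gave an adjusted p = 0.126 for oxidative phosphorylation, 0.338 for the activated fibroblast markers, 0.180 for cytokines and chemokines and 0.665 for the TGF-beta pathway. The latter was also at 0.0741, 0.0724 and 0.0576 without sham replicates 1 and 3 and TAC replicate 1. Leaving out TAC replicate 2 gave 0.224 for the endothelial markers, 0.0721 for the pericyte and smooth muscle markers, 0.410 for glycolysis and 0.0819 for the lymphocyte markers. Glycolysis was also at 0.122, 0.0552 and 0.0576 without sham replicates 1 and 2 and TAC replicate 1, at 0.0582 with the replicate block, 0.124 by fry and 0.0742 without the libraries over 30 CPM of Myl7, the lymphocyte markers at 0.0557 and 0.116 without sham replicates 1 and 3, and the pericyte and smooth muscle markers at 0.153 without sham replicate 2.

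**Figure D2:**
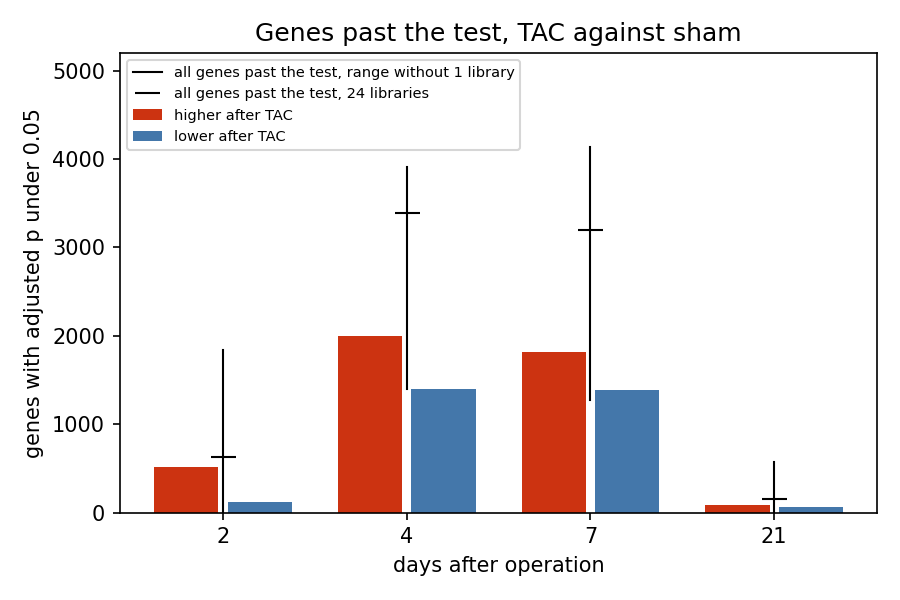
Numbers of genes with an adjusted p under 0.05 by edgeR, TAC against sham, by day: bars for genes higher and lower after TAC, dashes for their sum with 24 libraries and lines for the range when 1 library of the day is left out. The sum was 633, 3394, 3201 and 151, and at day 2 the line runs from 12 to 1835.

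The average over the 4 days used all 12 TAC and 12 sham libraries, compared within day. Rises were led by Sprr1a, a small proline-rich protein of stressed heart muscle and epithelia (6.23 ± 0.87, adjusted p = 1.41e-05), Cthrc1 (4.99 ± 0.68), Tnc (4.36 ± 0.45), Spp1 (4.07 ± 0.62), Timp1 (3.74 ± 0.46) and Col12a1 (3.39 ± 0.51). Falls were led by Kcnv2 (-1.89 ± 0.18, adjusted p = 4.74e-07), Cyp26b1, which breaks down retinoic acid (-1.62 ± 0.40), the chloride channel Clcn1 (-1.34 ± 0.196), the carboxylesterase Ces1d (-1.27 ± 0.23), Scn4b (-1.23 ± 0.21) and the galectin Lgals4 (-1.11 ± 0.21). In all 6319 genes passed the test, 3367 higher and 2952 lower, of which 734 and 60 by more than 2-fold. Genes past the test at all 4 days were 13 higher, namely Nppa, Nmrk2, Acta1, Nppb, Ankrd1, Mt2, 1500017E21Rik, Cyb561, Plcg2, Plp2, Hn1, Pdlim1 and Ehd4, and 3 lower, namely Map3k5, 9030617O03Rik and Pkd2l2. Days 4 and 7 shared 1165 higher genes, where 262 would be shared by chance, and 640 lower genes, where 140.2 would, with 5 genes in opposite directions. These expected numbers treat genes as independent, which they are not.

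Leaving out libraries moved these overlaps, an alternative chosen after seeing the data. The 16 genes of all 4 days became 5, 0 and 5 without sham replicates 1, 2 and 3 of day 2 (edgeR; 350 at an unadjusted p under 0.05 for the 0) and 77, 10 and 2 without the TAC replicates. For day 4 it was 8 and 27 without sham and TAC replicate 3, for day 7 it was 9, 7, 7 and 8 without sham replicates 1, 2 and 3 and TAC replicate 3, and for day 21 it was 2, 3 and 2 without the sham and 2, 64 and 2 without the TAC replicates. The 1805 genes of days 4 and 7 became 923 without TAC replicate 3 of day 4, 1185 and 988 without sham replicates 1 and 3 of day 7 and 824 and 1139 without TAC replicates 1 and 3.

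Whether the effect of TAC changed between days was tested as a difference of effects. It differed between days for 51 of 13816 genes, of which Tie1, Cdh5 and Aplnr are among the 20 endothelial markers. The effect of 40 of the 51 was lowest at day 2 and that of 34 highest at day 7. Ets1, a transcription factor of endothelial and immune cells, had log2 fold changes of -0.19, 0.0066, 0.70 and 0.22 at days 2, 4, 7 and 21 (adjusted p = 0.000901 for the difference). For Mest, an imprinted gene active in growing tissue, they were -0.12, 1.51, 2.66 and 0.56 (adjusted p = 0.00390). The genes of this paragraph other than Rsad2 and Trp53i11 were singled out after their values were seen. From day 4 to day 7 the effect rose for Ets1 (0.69 ± 0.10), Bcl6b (1.205 ± 0.202), Pcdh12 (1.02 ± 0.18), Nav3 (0.83 ± 0.15), Plxnd1 (0.70 ± 0.13) and 2900026A02Rik (0.62 ± 0.11) and fell for Lcn2 (-2.86 ± 0.50). From day 7 to day 21 it fell for Mest (-2.10 ± 0.36), Mastl (-3.19 ± 0.57), Adam19 (-1.09 ± 0.19), Arhgap18 (-0.76 ± 0.13) and Hist3h2a (-1.09 ± 0.20). It rose for the chemokine Cxcl14 (1.94 ± 0.35), Lrrc17 (1.63 ± 0.28), Lmcd1 (0.83 ± 0.15) and Rab3ip (0.56 ± 0.10). From day 2 to day 21 it rose for the interferon gene Rsad2 (1.47 ± 0.25, adjusted p = 0.0495) and for Trp53i11 (1.201 ± 0.16, adjusted p = 0.00304).

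From day 2 to day 4 edgeR called 0 genes, with 1215 at an unadjusted p under 0.05, while DESeq2 called 19 and voom with quality weights 70. The 51 genes whose effect differed between days became 20 without sham day 7 replicate 3, 21 without sham day 2 replicate 2 and 23 without sham day 2 replicate 1. It was 25 without sham day 7 replicate 1 or TAC day 7 replicate 3, 26 without sham day 7 replicate 2 or sham day 21 replicate 3 and 27 without sham day 2 replicate 3, sham day 4 replicate 1 or TAC day 21 replicate 1. It was 28 without sham day 4 replicate 3, 29 without sham day 21 replicate 2 and 32 without sham day 21 replicate 1. It was 113 and 33 without TAC day 2 replicates 1 and 2. It was 80 and 88 without TAC replicate 2 of days 4 and 7. The 7 genes of day 7 minus day 4 became 0 without sham day 4 replicate 3, TAC day 4 replicate 1, sham day 7 replicate 2 or TAC day 7 replicate 3, 1 without sham day 4 replicate 1, sham day 4 replicate 2 or sham day 7 replicate 3 and 2 without TAC day 4 replicate 2, sham day 7 replicate 1 or TAC day 7 replicate 2. Beside these counts of 0 by edgeR stood 850 to 983 genes at an unadjusted p under 0.05. The 9 genes of day 21 minus day 7 became 0 without any 1 sham replicate of day 7. They became 0 too without sham replicate 3 or TAC replicate 1 or 3 of day 21. The count was 1 without TAC day 7 replicate 3 or sham day 21 replicate 1 and 4 without sham or TAC replicate 2 of day 21. It was 17 without TAC day 7 replicate 2. Here the counts of 0 by edgeR stood beside 1278 to 2126 unadjusted. The 2 genes of day 21 minus day 2 became 1 without sham replicate 1 or 2 or TAC replicate 3 of day 2. They became 1 too without any 1 sham replicate or TAC replicate 1 of day 21. The count was 4 without TAC replicate 2 of either day and 9 without TAC day 21 replicate 3. It was 71 without TAC day 2 replicate 1. Trp53i11 passed the test without each library of days 2 and 21, and Rsad2 lost its call without 8 of these libraries.

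As lists, 11 of 32 differed between day 21 and day 2. Interferon response genes had a higher effect at day 21 (median difference 0.86, camera adjusted p = 2.49e-15, 0.139 with estimated correlation). So had endothelial markers (0.36, camera adjusted p = 7.49e-13, 0.0723 with estimated correlation). Glycolysis (0.16, camera adjusted p = 0.00200, 0.287 with estimated correlation), resident fibroblast markers (0.29, camera adjusted p = 0.00670, 0.458 with estimated correlation) and extracellular matrix (0.30, camera adjusted p = 0.0381, 0.955 with estimated correlation) had higher effects at day 21 too. At day 21 lower were the effects on immediate early genes (-0.59, camera adjusted p = 2.69e-09, 0.0877 with estimated correlation) and cell cycle (-0.92, camera adjusted p = 3.08e-08, 0.530 with estimated correlation). The effect was also lower for the unfolded protein response (-0.28, camera adjusted p = 1.56e-07, 0.139 with estimated correlation) and cytoskeleton (-0.34, camera adjusted p = 0.00561, 0.748 with estimated correlation). So it was for neutrophil markers (-0.95, camera adjusted p = 0.00907, 0.199 with estimated correlation) and cytokines and chemokines (-0.38, camera adjusted p = 0.00891, 0.748 with estimated correlation). Without TAC replicate 3 of day 2 the adjusted p was 0.0992 for resident fibroblast markers, 0.148 for neutrophil markers, 0.490 for cytokines and chemokines and 0.771 for the cytoskeleton, and without TAC replicate 2 of day 21 it was 0.177 and 0.135 for the latter pair. Without TAC replicate 3 of day 21 it was 0.0572 for resident fibroblast markers. The matrix list was at 0.162 and 0.614 without sham replicate 3 and TAC replicate 1 of day 2. It was at 0.0848, 0.144, 0.243 and 0.786 without sham replicates 1 and 3 and TAC replicates 1 and 3 of day 21. At 0.614 and 0.786 its difference was negative. In sham hearts 4 of the 23 immediate early genes also differed between days.

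Some lists were not called at any day with 24 libraries. The glucocorticoid and fasting response had camera adjusted p = 0.540, 0.542, 0.394 and 0.373 at days 2, 4, 7 and 21. The Schwann cell markers, of which Kcna1, a potassium channel of axons, fell at day 2 (-1.31 ± 0.29), had 0.112, 0.179, 0.990 and 0.2003. The skeletal muscle markers had 0.474, 0.757, 0.544 and 0.923. The blood cell transcripts, of which at day 4 Alas2, of heme synthesis in red cells, fell (-0.86 ± 0.23) and the platelet and macrophage chemokine Pf4 rose (0.54 ± 0.18), had 0.369, 0.394, 0.502 and 0.397. Pf4 lost its call without each of sham replicates 1 and 3 and the 3 TAC replicates of day 4, and Kcna1 without sham replicates 2 and 3 or TAC replicate 3 of day 2. Without 1 library of day 2 the glucocorticoid list was at 0.0115 (TAC replicate 3), the Schwann cell list at 0.00854 (sham replicate 1) and 0.0118 (TAC replicate 2) and the resident fibroblast list at 0.0191 (TAC replicate 2). At day 21 the latter was at 0.0445 and 0.0173 without sham and TAC replicate 2. The adipocyte markers had 0.624, 0.571, 0.801 and 0.966, and 0.0291 at day 4 without a filter. Of the 3 measured, edgeR called 0 at each day, with 1 lower at day 4 at an unadjusted p under 0.05, while DESeq2 called 0 and voom 1 at day 2. The resident fibroblast markers had 0.2000 at day 2 and 0.116 at day 21. All 24 hearts had the RNA of males, with at most 0.748 CPM of Xist and 111 to 149 CPM of Ddx3y.

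Sham hearts were compared with each other to see how far the controls moved over the days. Clock genes were prominent among the genes that differed. Arntl, the core clock activator, was at 9.30 ± 2.69, 21.1 ± 2.50, 1.61 ± 0.72 and 11.3 ± 2.39 CPM at days 2, 4, 7 and 21 (adjusted p = 0.000102). Per2 (adjusted p = 0.000182) and Per3 (0.00293), clock repressors, differed as well. The other genes with the smallest p were Adam19 (9.12e-05), Lrat (0.000965), Snora81 (0.00132), Gja1, the gap junction protein of heart muscle (0.00293), Ypel2 (0.00293), Snord15b (0.00367) and Cebpb (0.00397). In all 94 genes differed between the days in sham hearts. That count became 39, 41 and 37 without sham replicates 1, 2 and 3 of day 7. It was 57, 56 and 51 without those of day 4 and 51, 56 and 53 without those of day 21. It was 55 and 54 without sham replicates 1 and 2 of day 2.

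**Figure D3:**
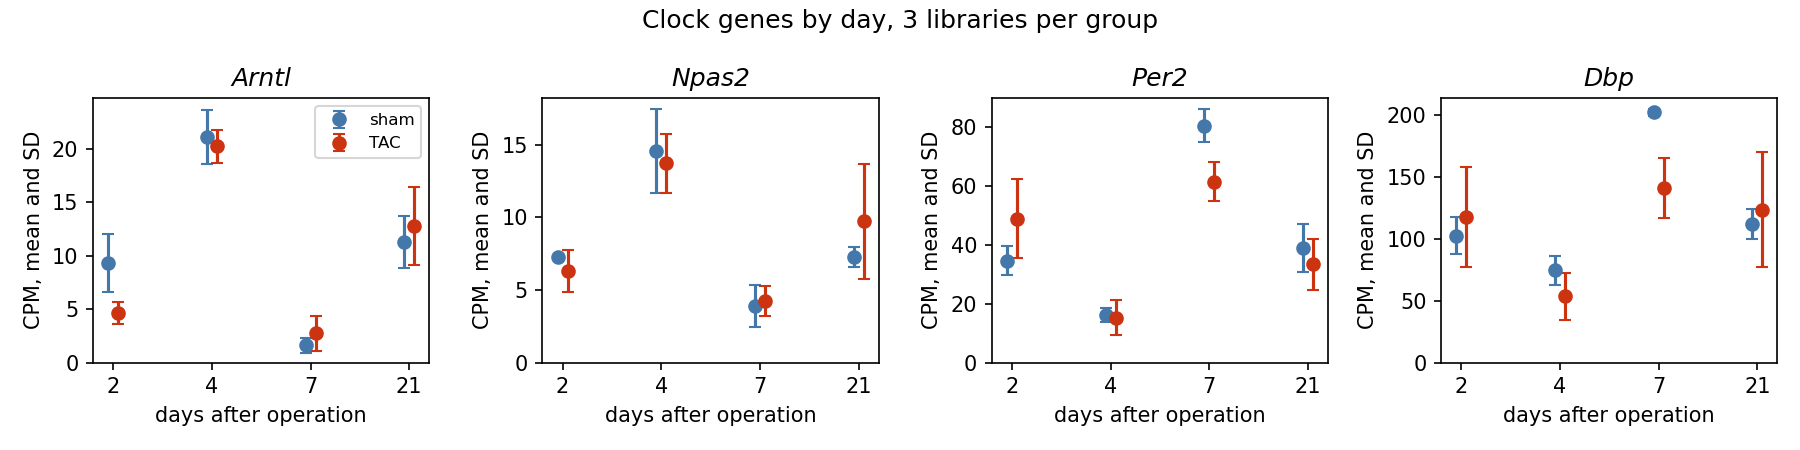
CPM, mean and SD of 3 libraries per group, of 4 clock genes by day in sham and TAC hearts. Arntl has means of 21.1 and 20.2 CPM at day 4 and of 1.61 and 2.72 CPM at day 7 in sham and TAC hearts.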

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

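The tests on splits of the libraries were planned, and the splits with the average effect of TAC taken out and the tests on endothelial genes, clock genes, TAC day 2 replicate 1 and Esr1 were chosen only after the results were seen.

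The effect of TAC differed between days for 51 genes by edgeR, for 7 genes between days 4 and 7, for 9 between days 7 and 21 and for 2 between days 2 and 21. As lists, 11 of 32 differed between days 2 and 21 with the preset correlation, by camera with an estimated correlation 0 did, with 6 at an unadjusted p under 0.05, and by fry 2 did. In 100 splits TAC and sham were dealt at random within each day, with each gene's average effect of TAC taken out. They gave at most 1 gene for the 51, the 7 and the 2, and 0 for the 9. Chance cannot be excluded by them, since effects of TAC in single days and hearts stay in and may lower their counts. The real counts also hang on single libraries (see the report). For the 0 genes between days 2 and 4 all 100 splits gave as many, with 1 as the highest. The planned splits, with the average effect left in, gave at most 20, 2074, 0 and 76 genes for the 51, 7, 2 and 9, with 6 of 100 as high as the 7 and 4 as high as the 9. They decide nothing here, since TAC labels kept unequally at 2 days turn the average effect into a difference. The average over days gave 6319 genes against at most 2634, and the sham hearts 94 against at most 11 when dealt to other days, 1 of 100 splits in both, so that chance can be excluded. At each day 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real counts were 633, 3394, 3201 and 151, and the highest of the others 0, 1, 0 and 0.

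Endothelial markers were lower after TAC at day 2 (median log2 fold change -0.27) and had a higher effect at day 7, by a median of 0.31, in 16 of 20 members. They made up 3 of the 51 genes whose effect differed between days, where 0.0738 would by chance (one-sided Fisher's exact p = 5.17e-05, 0.00165 adjusted over 32 lists). The interferon response passed too, with 2 of the 51 (adjusted p = 0.0315). Fisher's test treats genes as independent, which they are not, so that its p-values do not measure the spread between hearts. A difference between the sham groups is argued against by the median change of the list in sham hearts from day 2 to day 7, which was -0.014. A larger or smaller share of endothelial RNA alone would move the members alike, and stays open. At day 7, 3 members (Flt1, Vwf and Aqp1) passed the test as lower and 7 as higher, and 8 of 20 log2 fold changes were negative, but without sham replicate 3 or TAC replicate 1 of day 7 Vwf alone passed the test as lower, and without the latter the list was called (adjusted p = 0.0283). With an estimated correlation the change of the list between these days had an adjusted p = 0.129. A change of state of endothelial cells may underlie it too and was not tested.

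Clock genes differed between days in sham hearts, 10 of 17 past the test (one-sided Fisher's exact p = 2.43e-18, 7.78e-17 adjusted over 32 lists). The glucocorticoid (4 of 14), immediate early (4 of 23) and antioxidant (2 of 17) lists passed too (adjusted p = 3.05e-05, 0.000172 and 0.0466). Per1, 1 of the 4 glucocorticoid genes, is also a clock gene, and Fisher's test treats genes as independent, which they are not. The deviations of the clock genes from the mean over days ran together in sham and TAC hearts, with a correlation across genes and days of 0.874, where 10000 random lists of the same size gave at most 0.826. A steady course after the operation is argued against, since 0% of the clock genes past the test moved in 1 direction through the 4 days. Hearts collected at different times of day may explain this, and the labels give no time of collection. A response of the clock to surgery that both operations share was not tested.

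TAC day 2 replicate 1 lay near the sham hearts, with a slope of 0.0794 on the mean effect of TAC at the other 3 days, against 0.634 and 0.867 in the other TAC hearts of the day. A sham heart under a TAC label is argued against, since 3 of 4 markers (Nppa, Acta1 and Myh7, not Nppb) were above all 12 sham hearts. Its 2003 CPM of Esr1 were not a rise shared by TAC hearts, whose highest other value was 3.42 CPM, nor RNA of another tissue, since 0 further genes of at least 10 CPM reached 8 times the highest other library. A transgene that holds Esr1 sequence, as in a tamoxifen-inducible Cre recombinase, may be a source, in this heart or in RNA of another heart mixed in, and a milder constriction of this heart may be a cause of its small response. These are hypotheses without a test.

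Some genes had a count of 0 in every library and an RPKM past the test. Of 121 such genes tested on log2(RPKM + 1) with limma, 8 passed at day 4, 9 at day 7 and 1 at day 21.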

How the results depend on the processing

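The fits with Myl7 as a covariate, without the libraries over 30 CPM of Myl7 and, for genes shared between days, without 1 library were chosen only after the results were seen, and all others were planned.

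With RLE scaling (640, 3409, 3194 and 151 genes at days 2, 4, 7 and 21), the stricter filter (640, 3387, 3209 and 158) and no filter, the counts per day stayed within 1.5 times the main ones, and so did the average over days under all alternatives but the fold threshold. The counts at day 4 stayed so too, except with the fold threshold (1108) and without TAC replicate 3 of day 4. The 0 genes of day 4 minus day 2 stayed 0 where no value is given here.

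Counts that left this range, in genes by edgeR unless another tool is named, were as follows. RLE scaling gave 1 and no filter 6 for day 21 minus day 2. The replicate block gave 213 at day 2, 24 at day 21, 0 for day 7 minus day 4 (943 at an unadjusted p under 0.05), 0 for day 21 minus day 7 (1513 unadjusted) and 16 over all days. The fold threshold, which can only lower a count, gave 305 at day 2, 846 at day 7, 40 at day 21, 794 for the average and 3 for day 7 minus day 4. DESeq2 gave 461 at day 21, 19 for day 4 minus day 2, 60 for day 7 minus day 4, 74 for day 21 minus day 7, 59 for day 21 minus day 2, 299 over all days and 239 in sham hearts. Voom with quality weights gave 3407 at day 2, 5665 at day 7, 2036 at day 21, 70 for day 4 minus day 2, 106 for day 7 minus day 4, 674 for day 21 minus day 7, 500 for day 21 minus day 2, 1493 over all days and 814 in sham hearts. It weighted TAC replicate 1 of days 2 and 7, replicate 3 of day 4 and replicate 2 of day 21 lowest (0.311, 0.361, 0.396 and 0.405). Log2(RPKM + 1) gave 150 at day 2 and 21 for day 21 minus day 7, log2(RPKM + 0.1) gave 256 at day 2, and log2(RPKM + 1) without a filter gave 80 at day 2, 54 at day 21, 1 for day 4 minus day 2 and 36 in sham hearts. The 6 libraries of a day alone, with 4 residual degrees of freedom, gave 0 at day 2 (2418 unadjusted) and 30 at day 21. The Myl7 covariate gave 1552 at day 2, 1153 at day 21, 3 for day 21 minus day 7 and 25 for day 21 minus day 2. Without the 4 libraries over 30 CPM of Myl7 it was 0 at day 2 (1447 unadjusted), 892 at day 7, 3 at day 21, 0 for day 7 minus day 4 (996 unadjusted), 1 for day 21 minus day 7, 0 for day 21 minus day 2 (789 unadjusted), 0 over all days (1078 unadjusted) and 23 in sham hearts. In that fit sham day 2 held 1 library, assumed to vary like the other groups. Apart from the fold threshold and the smaller fits, the cause was not tested.

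Leaving out each library of the days compared gave 12 to 1835 genes at day 2, 1402 to 3910 at day 4, 1270 to 4132 at day 7, 7 to 575 at day 21, 5717 to 6803 for the average, 20 to 113 over all days and 0 to 1 for day 4 minus day 2. It gave 0 to 9 for day 7 minus day 4, 0 to 17 for day 21 minus day 7, 1 to 71 for day 21 minus day 2 and 37 to 65 in sham hearts. Lowest and highest came without sham replicate 2 and TAC replicate 1 at day 2, TAC replicates 3 and 2 at day 4, TAC replicates 1 and 2 at day 7 and sham replicate 3 and TAC replicate 2 at day 21, and the report gives the other libraries. The lists called ranged over 19 to 22, 18 to 20, 17 to 19 and 16 to 17 at the 4 days and 10 to 18 for day 21 minus day 2, where the extracellular matrix list reversed. The adjusted p of that list ranged over 7.14e-09 to 0.786, with 0.614 without TAC replicate 1 of day 2 and 0.786 without TAC replicate 3 of day 21. Calls gained without 1 library, beside those in the report, were at day 2 calcium handling (0.00802 to 0.0464, 3 libraries) and at day 4 the sarcomere (0.0402 and 0.0465). At day 21 they were the immediate early genes (0.0203 and 0.0482), atrial markers (0.01004 and 0.0404) and clock (0.0132). For day 21 minus day 2, 30 results of 14 lists did so: lymphocyte markers without 7 libraries (from 0.00102), macrophage markers (from 0.000692) and antioxidant genes (from 0.0370) without 3, oxidative phosphorylation (from 0.000213), hypertrophic (from 0.00199), glucocorticoid (from 0.00217), clock (from 0.0149), activated fibroblast (from 0.0166) and TGF-beta (from 0.0261) lists without 2, and branched-chain amino acids (0.00672), atrial (0.00946), TCA cycle (0.0202), fatty acid oxidation (0.0326) and pericyte (0.0370) lists without 1.

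With an estimated correlation 0 lists were called at days 2, 4, 7 and 21 and for day 21 minus day 2 (9, 6, 1, 2 and 6 at an unadjusted p under 0.05), where camera with the preset correlation called 20, 19, 18, 18 and 11 and fry 10, 19, 18, 3 and 2. The atrial list reversed at day 2 without the libraries over 30 CPM of Myl7, which by construction were high in its genes (adjusted p = 0.210, 0.01004 to 0.455 over the alternatives that kept all libraries). Of 160 list results, all kept direction and side of the threshold with RLE scaling, 159 with the block (not glycolysis at day 21, 0.0582) and 157 without a filter (not adipocyte markers at day 4, 0.0291, lymphocyte markers at day 7, 0.0199, and for day 21 minus day 2, 0.0167), and all of 155 on log2(RPKM + 1).

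Of the values of named genes, Lrrc15 at day 4 reversed on the RPKM, with -0.36 for log2(RPKM + 1), -0.42 for log2(RPKM + 0.1) and -0.36 without a filter, against 5.86 on the counts, and the cause was not tested. For named genes 601 of 603 results were the same with RLE scaling, 533 of 583 with DESeq2, where 50 passed the test anew, 457 of 603 with voom, where 142 passed anew and 4 no longer, and 543 of 593 with the block. They were 518 of 576 on log2(RPKM + 1), and 3328 of 3906 when a library was left out, where 499 no longer passed.

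Genes shared between days at adjusted p thresholds of 0.01 and 0.1, where fewer or more genes pass by construction, were 43 and 774 for days 2 and 4, 28 and 599 for days 2 and 7, 2 and 82 for days 2 and 21, and 593 and 2744 for days 4 and 7. They were 5 and 284 for days 4 and 21, and 4 and 290 for days 7 and 21. Leaving out a library gave 9 to 1268, 6 to 1004, 0 (by edgeR, 493 unadjusted) to 103, 824 to 2347, 7 to 417 and 5 to 370 for these pairs, and 0 (350 unadjusted) to 77 for all 4 days. In the simulated data, which had the same spread in sham and TAC hearts, 1.5-fold changes were found in 27% to 40% of genes.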

Other observations

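The 4 gene lists and the genes of this part were chosen after the results were seen. As lists, genes of NAD metabolism (11 measured), of serine and folate metabolism (15), of Wnt signals (12) and imprinted genes (16) did not pass in 16 tests, with the smallest camera adjusted p of 0.0602 for Wnt signals at day 4 and estimated-correlation values of 0.558 to 0.885. Single genes did, with a call that no single library of the day ended: Nmrk2 (4.01 ± 0.64, log2 fold change ± SE, adjusted p = 0.000423) and Nnt (-0.96 ± 0.19, 0.00142) at day 4. Others were Sfrp1, a Wnt inhibitor (2.23 ± 0.45, 0.00192), at day 4 and Cdkn1c, an imprinted growth inhibitor, at day 4 (-1.26 ± 0.23, 0.000984) and day 7 (-1.15 ± 0.22, 0.00161). Mest passed at day 4 (1.51 ± 0.25, 0.000580) and day 7 (2.66 ± 0.26, 1.33e-05). For each, all 3 TAC libraries lay beyond all 3 sham libraries of the day, which chance gives in 10% of genes.

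TAC day 21 replicate 2 had a slope of 0.0763 on the mean effect of TAC at the other 3 days, against 0.426 and 0.648 in the day's other TAC hearts. In TAC hearts slopes were 0.864 to 1.55 at day 4 and 0.580 to 1.18 at day 7, and -0.125 to 0.0817 in sham hearts. Sham day 4 replicate 3 held 1279 CPM of Scd1, 624 of Fasn, 100.96 of Car3, 36.2 of Cfd, 14.2 of Ucp1 and 13.4 of Adipoq, genes of fat cells, against at most 52.0, 78.1, 8.43, 6.40, 0.058 and 1.60 in the other libraries. Myl7 was at 94.8 and 37.2 CPM in sham day 2 replicates 3 and 2, 69.9 in sham day 21 replicate 2 and 69.2 in TAC day 7 replicate 1, and at most 13.6 in the others.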
